A study of Mus musculus with 24 samples.

How the data were processed

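Placental RNA from pregnant mice was sequenced in 24 libraries. Per the labels, 8 groups of 3 libraries crossed diet (Control or MMV), housing temperature (22C or 33C) and fetal sex (female or male). MMV is the label's name for the micronutrient-restricted diet that the design text calls 70MMV and the series title describes as micronutrient insufficiency; its composition is not given in the sources used here. The label field that holds the diet is named for temperature, and the diet was read from its values and from the group label. Per the design text, 6 mice were used per diet-temperature condition, placental sex was read by genotyping fetal tails, and placental RNA was pooled into 3 pools per sex. The labels' extract protocol gives 4 libraries per group, which the 3 listed per group do not match. Each library is therefore a pool of several placentas, and its spread covers pools, not single placentas. Neither the number of placentas in a pool nor whether the female and male pools of a condition share dams is stated. If they do, the 6 libraries of a condition are not 6 independent samples and p-values over them are too small. Replicate numbers were given in accession order and name a library only.

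Per the labels' protocols, RNA was purified on columns with DNase digestion and libraries were made with a stranded TruSeq kit. Per the submitters' processing notes, STAR, R 4.05, limma and the mouse genome build mm10 were used, with no role given for limma. The counting program, gene annotation and strand setting are not given in the sources used here. Counts of overlapping or antisense genes and of near-identical families (Psg, Prl2c, Hba) are therefore uncertain, since the counting could split or drop their reads. The deposited table holds estimated counts per gene, not scaled between libraries: whole numbers except in 2 genes with identical values ending in 0.5 in 12 libraries, which were rounded. All 24 columns were matched to libraries by title. The table has 35515 genes, of which 10253 had no count in any library. Of the gene identifiers, 35478 were matched to a table of gene names and 37 were not. A further 26 symbols had been turned into dates and were restored through the identifier, and 21 entries shared a symbol with another. The 13 mitochondrially encoded genes all hold 0 counts, so the list of mitochondrially encoded transcripts could not be tested. Coordinates are from GENCODE release 21 for mouse, on GRCm38, the assembly named mm10; 17158 of the 17160 genes tested were found in it.

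Total counts ran from 16456546 to 37261002 per library with a median of 24.8 megacounts. Within groups, 24 replicate pairs had a Pearson correlation of log2 CPM of 0.961 to 0.992 across genes, which are not independent replicates. Their counts differed by 23.3 to 136 times the sampling noise (chi-square per degree of freedom), so no library repeats another. Intervals and floors given for counts of 0 use 3 counts and cover counting error only.

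Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (robust quasi-likelihood F test, TMM factors, 8 group means, 16 residual degrees of freedom) after filterByExpr, which kept 17160 genes with about 10 counts (0.404 CPM at the median depth) in at least 3 libraries. The biological coefficient of variation was 0.221. Contrasts averaged the groups with equal weight over the factors they were not about, so a log2 fold change can differ from the ratio of the printed means, which are arithmetic means of CPM (counts scaled by library size and TMM factors). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each of 11 comparisons, and in 10 further comparisons within a single sex, where 3 libraries faced 3. Adjusted p-values below are from edgeR unless another tool is named. Errors of log2 fold changes are standard errors (SE), and errors of means are SD.

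Before the data were examined, 45 gene lists were fixed, along with the comparisons and the rule for named genes. That rule takes the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1, up to 4 members of each list described by smallest p, a fixed set of heat shock, cold-inducible, metal-responsive and sex-linked genes, and the 5 genes with the smallest p in interactions and simple effects. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 42 lists with enough members tested. Camera with an estimated correlation and fry were the alternatives. Fry asks whether a list's genes move one way on balance and does not compare the list with other genes. A list mean is the mean over members of log2 CPM centred over the 24 libraries. After principal components had been seen, 2 further lists (uterine gland epithelium and myometrium) and 7 alternatives were added.

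Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom with sample quality weights, other filters on low counts, sex as an additive term, the erythroid list mean as a covariate, only the groups compared, other thresholds, and each library left out in turn. On counts simulated from these libraries with 200 changed genes, edgeR recovered 83% of 1.5-fold and 92% of 2-fold changes for diet (16886 genes; 3.31% of its calls false), 71% and 97% for heat (16875 genes; 5.62% false), 67% and 83% for diet at 33C (16892 genes; 3.85% false), 62% and 90% for heat on the control diet (16897 genes; 5.59% false), and 35% and 72% for diet at 33C in females (16893 genes; 7.76% false). The share of false calls by DESeq2 was 7.14% for diet and 18.1% for heat on the control diet. Camera called 2 of 2 shifted lists and 0 of 20 unchanged ones, but the genes were simulated independently, so this leaves out the correlation between genes of these pools and gives no rate of false list calls for them. For the same reason the shares of genes recovered and falsely called hold for independent genes and give no rates for these pools. Random splits of the real libraries called up to 102 genes for heat and 485 for heat on the control diet, though 97 and 98 of 99 called 0.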

Results

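The transcriptome of the mouse placenta was measured by RNA sequencing in 24 pooled libraries, 3 for each of 8 groups of diet (Control or the micronutrient-restricted MMV diet), housing temperature (22C or 33C) and fetal sex. Every comparison of diet, temperature or sex set 12 libraries against 12, and every comparison between diet-temperature conditions set 6 against 6. Total counts ran from 16456546 to 37261002 per library. Mean depth per group was lowest in MMV.33C.Male, at 20.5 ± 3.67 megacounts, and highest in MMV.22C.Female, at 30.3 ± 6.02 megacounts (SD, n = 3). The most abundant transcripts were mostly placental. Psg21, a pregnancy-specific glycoprotein, took 1.82% of counts, Tpbpa, a marker of the junctional zone, 1.61%, and Prl3b1, placental lactogen, 1.59%. Gm42418 took 1.18%, and Afp, a member of the yolk sac list, 1.05%. The yolk sac list mean ran from -1.42 in MMV.33C.Female 1 to 0.79 in MMV.33C.Female 2. Counts of 5 genes that overlap or resemble ribosomal RNA and other abundant structural RNAs (Gm42418, Gm26917, Lars2, Rmrp and Rpph1, chosen after their values were seen) differed between groups. They made up 3.75% ± 0.668 of counts in MMV.22C.Female and 0.183% ± 0.0207 in MMV.22C.Male (SD, n = 3). In the other groups the mean share lay between 0.456% and 2.11%.

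Fetal sex labels were checked first with sex-linked transcripts. Ddx3y, Uty and Eif2s3y, all on the Y chromosome, had 0 counts in all 12 female libraries, while Kdm5d had 1 count in MMV.33C.Female 1. In the 12 male libraries Ddx3y stood at 34.4 ± 4.93 CPM, Uty at 8.44 ± 1.61 and Eif2s3y at 28.4 ± 9.67 (SD). Against a floor of 3 counts over the 12 female libraries, 0.00932 CPM, these were at least 3692-, 906- and 3048-fold higher in males. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254, GRCm38), was at 585 ± 109 CPM in female and 88.2 ± 23.4 CPM in male libraries. Male pools held it at 52.4 to 134 CPM. Per the design text sex was read from fetal tails, and each library's Y-linked counts matched its label.

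The effect of heat was asked by comparing the 12 libraries from 33C with the 12 from 22C. Dhrs7, a short-chain dehydrogenase (ENSMUSG00000021094, chromosome 12, 72650353 to 72664909), rose from 19.2 ± 1.13 to 22.9 ± 1.32 CPM (SD, n = 12). Its log2 fold change was 0.25 ± 0.04 (SE) with an adjusted p of 0.0349, and it was above the 22C mean in 12 of 12 pools. No heat shock chaperone passed the test. Hspa1a, the inducible 70 kDa chaperone, was at 15.7 ± 6.37 CPM at 33C and 13.6 ± 3.23 at 22C, and Hspa1b, Hsph1 and Hspa8 had log2 fold changes of 0.07, -0.03 and -0.05. Of 27 chaperones, 10 had positive and 17 negative values with a median of -0.03. Of these 0 were called over all genes and 0 adjusted over the list alone, and camera gave an adjusted p of 0.868. The cold-inducible Cirbp and Rbm3 had log2 fold changes of -0.04 and -0.03, and the metallothioneins Mt1 and Mt2 0.17 and 0.19, none called.

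Immune lists had the largest values in the heat comparison, and none of their members was called over all genes. The 17 inflammatory genes all had positive values, with a median log2 fold change of 1.21, and 15 rose adjusted over the list alone. Cxcl2, a neutrophil-attracting chemokine, was at 13 ± 26.7 CPM at 33C and 0.369 ± 0.164 at 22C (SD, n = 12), above the 22C mean in 9 of 12 pools. Il1b, a pyrogenic cytokine, was at 13.5 ± 30.7 and 0.65 ± 0.176, in 8 of 12 pools. At 33C the SD exceeded the mean, with high values in a few pools, and the adjusted p was 0.291 for both. The 19 interferon response genes had a median of 0.40, with 9 rising adjusted over the list alone. The 7 neutrophil markers had a median of 0.97, with 4 rising adjusted over the list alone, among them S100a9 (1.98 ± 0.50). Of 16 macrophage markers 14 had positive values and 2 rose adjusted over the list alone. The 11 natural killer and T cell markers were all positive with a median of 0.56. Without the 4 libraries with low uterine gland scores that median was 0.17, still with 11 positive. Camera called the inflammatory, interferon, neutrophil and macrophage lists upward (adjusted p = 1.82e-11, 1.67e-11, 0.00113 and 4.04e-05). With an estimated correlation all of these calls were lost (adjusted p = 0.416, 0.442, 0.416 and 0.587 with an estimated correlation). Without Control.33C.Female 2, MMV.33C.Male 1 and MMV.33C.Male 2, the 3 libraries with high inflammatory scores, the inflammatory, interferon and neutrophil medians were 0.24, 0.15 and 0.34. This left a single pool in MMV.33C.Male. Control.33C.Male 2 (list mean 1.21) and Control.33C.Female 3 (1) were kept, though above the highest list mean at 22C (0.29).

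Nuclear-encoded genes of the respiratory chain had slightly lower values at 33C. Of 35 tested, 32 were negative, with a median log2 fold change of -0.07. None was called over all genes, and 5 fell adjusted over the list alone, among them Ndufs8, a complex I subunit (-0.15 ± 0.03, 24.3 ± 1.5 against 26.9 ± 1.81 CPM, 12 of 12 pools), and Cox7a2, a complex IV subunit (-0.12 ± 0.03, 11 of 12 pools). Camera called the list downward (adjusted p = 2.77e-09, and adjusted p = 0.353 with an estimated correlation), and it was the only list that fry called for heat (adjusted p = 0.0312). The endoplasmic reticulum stress list had 18 of 19 negative values with a median of -0.13 and 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.00726, and adjusted p = 0.824 with an estimated correlation). The junctional zone list had 21 of 23 negative values, a median of -0.13 and 0 called by either adjustment (0.00726, and 0.824 with an estimated correlation). Both lost their camera call without the 4 libraries with low uterine gland scores, a set chosen after seeing the data.

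For heat edgeR thus called 1 of 17160 genes, while 1618 had an unadjusted p under 0.05 against 858 given by chance. DESeq2 called 101 genes, and limma-voom with quality weights 1. The count was 2 without Control.33C.Female 2. It was 1 without Control.22C.Male 2, Control.33C.Female 3, Control.33C.Male 3, MMV.22C.Female 3, MMV.33C.Female 3 or MMV.33C.Male 2, and 0 without each of the other 17 libraries. It was also 0 with library size alone as the scaling, without a filter on low counts, and with the erythroid, uterine gland, junctional zone or rRNA-related covariate.

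The MMV diet was associated with the largest number of differences. Among the genes that rose on MMV were Tfrc, the transferrin receptor through which cells take up iron, from 181 ± 76.7 to 494 ± 299 CPM (SD, n = 12), and Lipg, endothelial lipase, from 45.7 ± 14.8 to 108 ± 65.7. Dlx3, a transcription factor of the labyrinth, where maternal and fetal blood exchange, rose from 20.2 ± 6.94 to 47.6 ± 23.4. Their log2 fold changes were 1.48 ± 0.38, 1.23 ± 0.32 and 1.23 ± 0.30 (adjusted p = 0.0416, 0.0414 and 0.0353), with 10, 10 and 11 of 12 MMV pools above the Control mean. Trp63, an epithelial stem cell factor (1.46), Slc35f2 (1.22), Slc26a7, an anion exchanger (1.22), Gata1, an erythroid factor (1.21), and Wnk3, a kinase of ion transport (1.21), rose as well. Mmp12, macrophage elastase, fell from 24.7 ± 6.30 to 13.5 ± 3.70 CPM, Prl3a1, a prolactin family hormone of the junctional zone, from 847 ± 191 to 498 ± 118, and Fbln1, a matrix protein, from 602 ± 78.1 to 384 ± 65.6. Their log2 fold changes were -0.85 ± 0.14, -0.77 ± 0.14 and -0.65 ± 0.10 (adjusted p = 0.0162, 0.0189 and 0.0161), and each was below the Control mean in 12 of 12 MMV pools. Derl3, which acts in disposal of misfolded proteins (-0.75), Lgi2 (-0.65), Dclk2, a doublecortin-like kinase (-0.62), and Rgs4, a regulator of G protein signalling (-0.59), also fell.

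**Figure D1:**
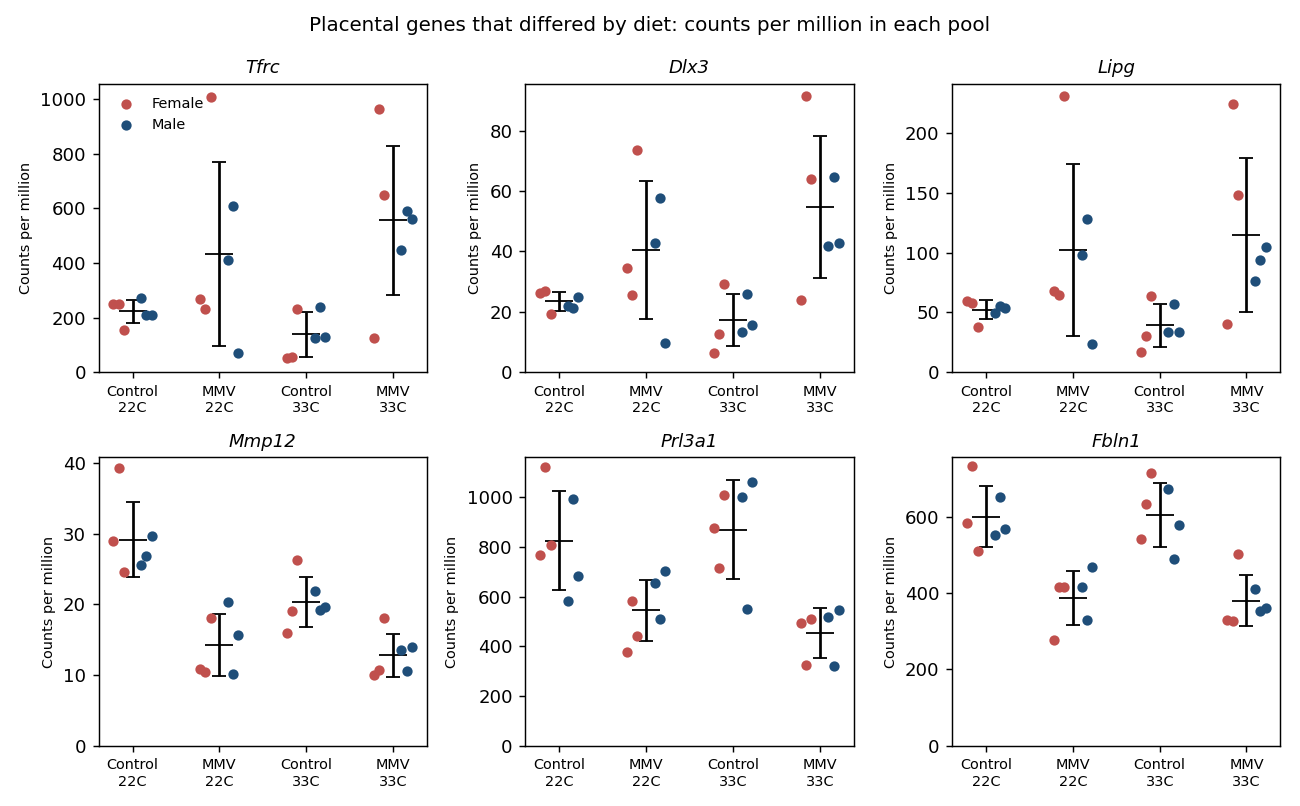
CPM of 3 genes that rose (Tfrc, Dlx3, Lipg) and 3 that fell (Mmp12, Prl3a1, Fbln1) on the MMV diet, on linear axes from 0, with a point for each pool, coloured by fetal sex, and the mean and SD of the 6 pools of each diet-temperature condition. MMV pools were spread widely for the genes that rose, with an SD of 299 CPM for Tfrc against 76.7 in Control pools, and less so for those that fell, with an SD of 65.6 CPM for Fbln1 against 78.1.

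In the annotation of GRCm38 the genes that rose lie at chromosome 16, 32608920 to 32632794 (Tfrc, ENSMUSG00000022797), chromosome 18, 74939322 to 74961263 (Lipg, ENSMUSG00000053846), and chromosome 11, 95120119 to 95125296 (Dlx3, ENSMUSG00000001510). Those that fell lie at chromosome 9, 7344381 to 7369499 (Mmp12, ENSMUSG00000049723), chromosome 13, 27259436 to 27276667 (Prl3a1, ENSMUSG00000038883) and chromosome 15, 85205949 to 85286535 (Fbln1, ENSMUSG00000006369). Counts cover whole genes.

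In all, edgeR called 541 genes for diet, 378 higher and 163 lower on MMV, with 3671 at an unadjusted p under 0.05. With library size alone the split was 1593 higher and 130 lower. The number was 3 with the rRNA-related level as a covariate, 4 with the erythroid and 0 with the labyrinth list mean. It was 1 without the 4 libraries with low uterine gland scores. The 3 with high inflammatory scores were also left out. This leaves a single pool in MMV.33C.Male, so only effect sizes are given for that set. The median ratio of the 541 genes' log2 fold changes to those with all libraries was 102% and 100% in these sets, 95.7% with the rRNA-related, 72.8% with the erythroid and 59.5% with the labyrinth covariate. These covariates and sets, apart from the erythroid one, were chosen after seeing the data. Leaving out Control.22C.Female 1, 2 or 3 gave 325, 236 or 105 genes, and Control.22C.Male 1, 2 or 3 gave 228, 112 or 278. Without Control.33C.Female 1, 2 or 3, 116, 490 or 579 were called, and without Control.33C.Male 1, 2 or 3, 125, 1054 or 73. Leaving out MMV.22C.Female 1, 2 or 3 gave 442, 1025 or 170, and MMV.22C.Male 1, 2 or 3 gave 117, 41 or 1355. Without MMV.33C.Female 1, 2 or 3, 1673, 40 or 180 were called, and without MMV.33C.Male 1, 2 or 3, 586, 62 or 186.

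Among the gene lists, the endoplasmic reticulum stress list, which holds chaperones and folding enzymes of the secretory pathway, was lower on MMV. All 19 members had negative values with a median log2 fold change of -0.30, 4 fell over all genes and 15 fell adjusted over the list alone. The 4 were Manf (-0.41 ± 0.09), Pdia4 and Pdia3, both disulfide isomerases (-0.49 ± 0.11 and -0.30 ± 0.07), and Creld2 (-0.58 ± 0.15). Creld2 fell from 124 ± 31.4 to 82.3 ± 21.9 CPM (SD, n = 12). The 4 had adjusted p from 0.0302 to 0.038 and 11 or 12 of 12 pools below the Control mean. Camera called the list downward (adjusted p = 2.84e-09, and adjusted p = 0.549 with an estimated correlation), and fry gave an adjusted p of 0.0601. Across libraries the list mean moved with that of the junctional zone (deviations from group means, Pearson r = 0.784, permutation p = 0.006; Spearman rho = 0.664, permutation p = 0.01; 1 relation). The r was 0.655 without Control.33C.Female 2 and Control.33C.Female 3. This pair of lists was not among the planned tests, and the permutation p does not account for its choice. The median of the endoplasmic reticulum stress list was -0.14 with the junctional zone list mean as a covariate (added after seeing the data), -0.33 with the labyrinth and -0.36 with the erythroid one. The junctional zone list had 20 of 23 negative values with a median of -0.20. Here 3 members fell over all genes (Prl3a1, Prl8a8 at -0.47 and Tpbpa at -0.49) and 4 adjusted over the list alone (camera adjusted p = 0.00293, and adjusted p = 0.658 with an estimated correlation). Of 12 trophoblast giant cell markers 0 were called over all genes, while 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0162, and 0.658 with an estimated correlation). Reads of the Psg, Prl2c and other near-identical families in these lists are uncertain.

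Amino acid transporters were higher on MMV, with 16 of 17 positive and a median log2 fold change of 0.28. Over all genes 5 rose, and 12 rose adjusted over the list alone. Slc7a5, the large neutral amino acid carrier, rose from 97.8 ± 27.9 to 198 ± 93.6 CPM (1.01 ± 0.26, adjusted p = 0.0398, 11 of 12 pools). Slc7a1, the cationic carrier, rose from 163 ± 34.4 to 270 ± 89.5 (0.73 ± 0.17, adjusted p = 0.0352, 11 of 12 pools). Slc1a4 rose by 0.28 and Slc1a3 by 0.61. Camera called the list upward (adjusted p = 8.77e-07, and adjusted p = 0.549 with an estimated correlation). Labyrinth markers had 11 of 14 positive values and a median of 0.34. Dlx3 and Lepr, the leptin receptor (0.35 ± 0.09), rose over all genes and 7 rose adjusted over the list alone. Gcm1, the syncytiotrophoblast factor, missed the threshold (1.77 ± 0.55, adjusted p = 0.0752, 9 of 12 pools). Camera called that list upward (adjusted p = 7.88e-04, and adjusted p = 0.549 with an estimated correlation). The amino acid transporters moved with the labyrinth markers, and their median was 0.09 with the labyrinth list mean as a covariate.

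Lists of micronutrient handling genes were tested for diet. Of 22 iron handling genes 2 rose, Tfrc and Slc40a1, the iron exporter ferroportin (0.63 ± 0.14, adjusted p = 0.0298, 194 ± 57.7 against 125 ± 13.9 CPM, 11 of 12 pools), and 4 rose adjusted over the list alone. Of 30 genes of folate, vitamin B12 and one-carbon metabolism 1 rose by either adjustment. It was Cd320, the receptor for transcobalamin-bound vitamin B12, which rose from 46.4 ± 14.6 to 100 ± 54.3 CPM (1.09 ± 0.28, adjusted p = 0.0437, 10 of 12 pools). Of 21 genes for water-soluble vitamins 3 rose, Slc5a6, the biotin and pantothenate carrier (0.75), Slc19a2, a thiamine carrier (0.30), and Hlcs, which attaches biotin to enzymes (0.46), and 1 fell, Btd, which frees biotin (-0.20). That list had 4 higher and 1 lower adjusted over the list alone. Of 18 zinc and copper genes 1 rose, the zinc importer Slc39a10 (0.49), with 2 higher and 1 lower adjusted over the list alone. The metallothioneins Mt1 and Mt2 had log2 fold changes of 0.00 and 0.03. Camera called none of these 4 lists (adjusted p = 0.104, 0.254, 0.101 and 0.178). The rises moved with the labyrinth and erythroid markers. With the labyrinth list mean as a covariate none of these genes was called, and the log2 fold changes of Tfrc, Slc40a1, Cd320 and Slc5a6 were 0.21, 0.23, 0.19 and 0.15 (0.54, 0.38, 0.43 and 0.34 with the erythroid one). Of 18 selenoproteins Gpx2 fell (-0.53), and 3 fell adjusted over the list alone (camera adjusted p = 0.0501). Among 22 imprinted genes Grb10, a brake on growth factor signalling (0.41), and Peg10, needed for placental growth (0.32), rose over all genes and adjusted over the list alone (camera adjusted p = 0.346).

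Other lists called by camera for diet had few or no called genes. The 15 erythroid markers had a median of 0.46, with 0 called over all genes and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00119, and 0.658 with an estimated correlation). The 19 interferon response genes were all negative with a median of -0.27, with 0 called and 2 lower adjusted over the list alone (7.88e-04, and 0.658 with an estimated correlation). The interferon list mean stood apart in Control.33C.Female 2 (1.62), and without the 3 libraries with high inflammatory scores the median was -0.23, with 2 of 19 positive. Among 27 heat shock chaperones, Serpinh1, the collagen chaperone, fell (-0.36 ± 0.09, adjusted p = 0.0358, 11 of 12 pools), the only one by either adjustment, and the list had a median of -0.07 (0.0162, and 0.658 with an estimated correlation). Hsph1 was at 81.1 ± 17.6 on MMV and 98.3 ± 15.1 CPM on Control (adjusted p = 0.199). Glucose and lipid uptake genes had Lipg called and 7 higher and 2 lower adjusted over the list alone (0.0239, and 0.549 with an estimated correlation). The ATF4 target list, with Slc7a5 called and 3 higher adjusted over the list alone, had a camera adjusted p of 0.039, cholesterol synthesis, with 0 of 20 by either adjustment, 0.0132, and fatty acid oxidation, with 0 of 18 by either, 0.0239 (0.658, 0.768 and 0.658 with an estimated correlation). No list was called for diet with an estimated correlation (lowest adjusted p = 0.549) or by fry (lowest adjusted p = 0.0571).

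**Figure D2:**
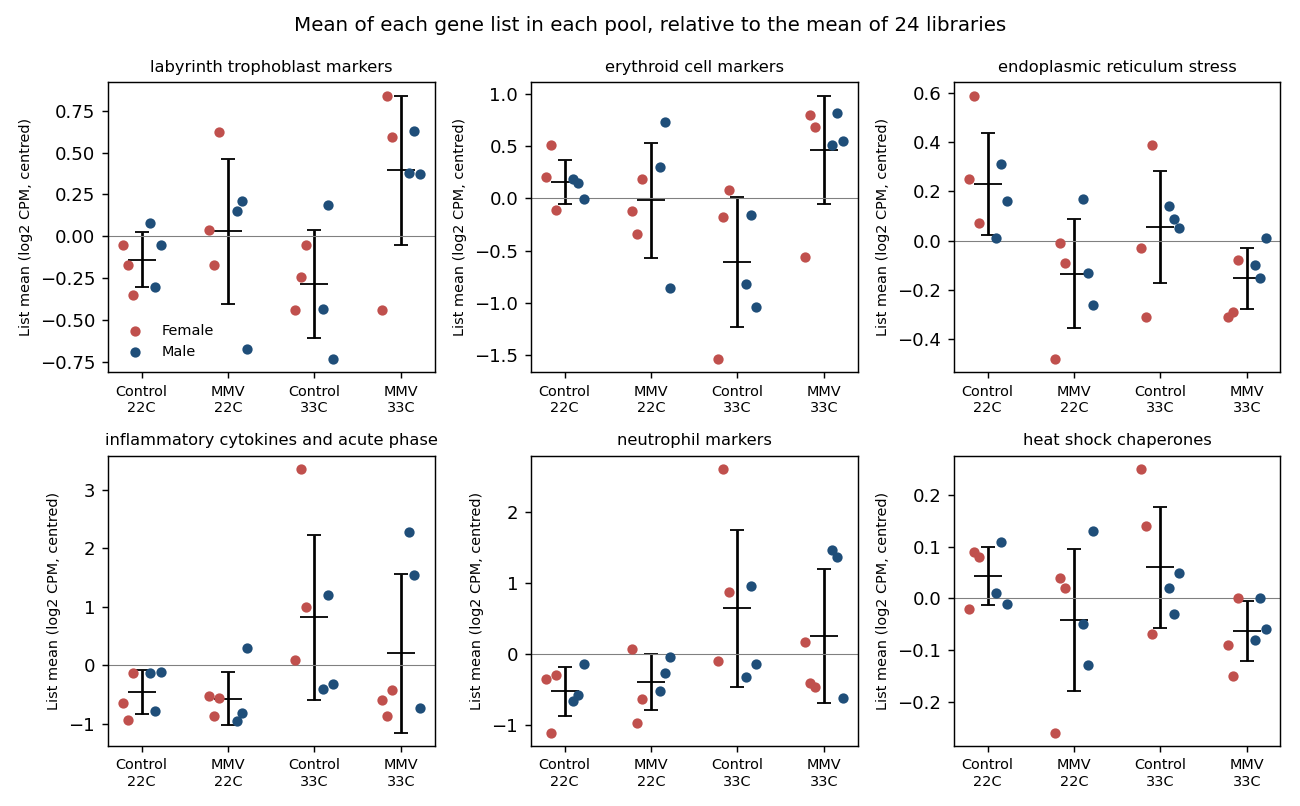
Means of 6 gene lists (log2 CPM, centred on the mean of 24 libraries) in each pool, with a point per pool coloured by fetal sex and the mean and SD of the 6 pools of each diet-temperature condition. Labyrinth and erythroid means lay at 0.40 ± 0.44 and 0.47 ± 0.52 in MMV pools at 33C and at -0.28 ± 0.32 and -0.61 ± 0.63 in Control pools at 33C, and the inflammatory mean reached 3.35 in a Control pool at 33C against a highest value of 0.29 at 22C.

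The series title asks whether micronutrient insufficiency worsens the response to heat, which is the interaction of diet and heat. No gene was called for it by edgeR (smallest adjusted p = 0.488), with 1312 at an unadjusted p under 0.05, 10 called by DESeq2 and 1 by limma-voom. The 5 genes with the smallest p were Sprr2d (-4.31 ± 0.84, at very low counts), Usp2, a deubiquitinase tied to the clock (0.42 ± 0.09), Cdhr4 (0.88 ± 0.19), Crlf1, a cytokine-like factor (1.52 ± 0.33), and Tbc1d1, which acts in glucose uptake (-0.48 ± 0.11). Tfrc had an interaction of 1.10 ± 0.75 (adjusted p = 0.721). The erythroid list had an interaction median of 1.05, with 14 of 15 positive, 0 called over all genes and 3 adjusted over the list alone. The interferon list had a median of -0.51, with 19 of 19 negative and 0 by either adjustment, and its list mean stood apart in Control.33C.Female 2 (1.62) and MMV.33C.Male 1 (0.84). Without the 3 libraries with high inflammatory scores the median was -0.41, still with 0 positive. Cytosolic ribosomal proteins had a median of 0.15, with 36 of 36 positive and 0 by either. Camera called them (adjusted p = 9.48e-10, 5.26e-05 and 9.48e-10), and none held (adjusted p = 0.618 for each with an estimated correlation).

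Heat on each diet taken alone gave 0 called genes. On the Control diet 1549 genes had an unadjusted p under 0.05, DESeq2 called 67 and limma-voom 4. There edgeR called 1 without Control.22C.Male 1 or Control.22C.Male 3. Dhrs7 was at 23.4 ± 1.15 CPM at 33C and 18.9 ± 1.13 at 22C (SD, n = 6), a log2 fold change of 0.31 ± 0.05 (adjusted p = 0.118, 6 of 6 pools), and Ch25h, cholesterol 25-hydroxylase, had 2.19 ± 0.42 (adjusted p = 0.249, 6 of 6 pools). Sprr2d, Vti1b and Usp2 completed the smallest p-values. On MMV 1385 genes had an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 0. The smallest p-values there were those of Nhs (-0.41 ± 0.08), Atp5k, a subunit of ATP synthase (-0.28 ± 0.06), Lsm6 (-0.24 ± 0.05), Tuba1c (-0.31 ± 0.06) and Slc29a2, a nucleoside carrier (0.52 ± 0.11), each with an adjusted p of 0.494 and the same direction in 6 of 6 pools. The erythroid list had a median of -0.76 for heat on Control and 0.29 on MMV, with 0 called over all genes in both, and 0 and 3 adjusted over the list alone (camera adjusted p = 5.03e-08 and 0.00248, and adjusted p = 0.478 and 0.635 with an estimated correlation).

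The effect of diet was also taken at each temperature. At 33C the genes with the smallest p were Fyn, a tyrosine kinase (0.32 ± 0.05), Crlf1 (1.5 ± 0.24), Car5b, a mitochondrial carbonic anhydrase (0.44 ± 0.07), Aplp1 (-0.62 ± 0.10) and Pnpla3, a lipase (1.03 ± 0.17), each with an adjusted p of 0.0182 and the same direction in 6 of 6 MMV pools. The 15 erythroid markers had a median of 1.03, with 4 rising over all genes and 12 higher and 1 lower adjusted over the list alone. Their list mean was 0.47 ± 0.52 in MMV and -0.61 ± 0.63 in Control pools at 33C (SD, n = 6), against 0.16 ± 0.21 in Control pools at 22C. Among the pools at 33C it was lowest in Control.33C.Female 1 (-1.54), Control.33C.Male 3 (-1.04) and Control.33C.Male 1 (-0.82). Without any 1 of these 3 pools 0 genes were called at 33C by edgeR. Alas2, the erythroid enzyme that starts haem synthesis, rose from 75.1 ± 37.4 to 199 ± 63.6 CPM (SD, n = 6; 1.40 ± 0.36, adjusted p = 0.0446, 6 of 6 pools). The embryonic globins Hbb-y and Hba-x rose by 2.72 and 2.09 and Tspo2 by 1.60. Hmgcs2, the enzyme that commits acyl groups to ketone bodies, rose from 13.9 ± 5.82 to 32.8 ± 4.15 (1.28 ± 0.24, adjusted p = 0.0229, 6 of 6 pools), and Slc25a20 by 0.24. They were the 2 called among 18 fatty acid oxidation and PPAR targets, where 5 rose and 1 fell adjusted over the list alone.

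Some single transport and labyrinth genes rose at 33C. Slc1a5, a glutamine carrier (0.66 ± 0.14, adjusted p = 0.0294, 6 of 6 pools), and Slc7a5 (1.40 ± 0.36) were called among 17 amino acid transporters, of which 8 rose adjusted over the list alone. Dlx3 (1.67 ± 0.42) and Lepr (0.53 ± 0.12) were called among 14 labyrinth markers, of which 7 rose adjusted over the list alone. The endothelial factors Erg (0.40) and Sox17 (0.35) were called among 20 endothelial markers, with 3 adjusted over the list alone. Oas1a (-0.57), Selenon (-0.43) and Abcg1 (-0.49) fell, as the single member called of the interferon, selenoprotein and glucose and lipid uptake lists. In these lists 11 fell, 3 fell, and 8 rose and 2 fell adjusted over the list alone. The interferon median of -0.53 was -0.40 without the 3 libraries with high inflammatory scores, among them Control.33C.Female 2, whose list mean of 1.62 stood apart. Water-soluble vitamin genes had 0 called and 5 higher and 1 lower adjusted over the list alone. Tfrc (2.04) and Cd320 (1.46) missed the threshold at 33C alone (adjusted p = 0.0515 and 0.0552). Camera called the erythroid, amino acid transporter, labyrinth, fatty acid oxidation and interferon lists (adjusted p = 4.62e-07, 4.47e-05, 9.68e-04, 0.00193 and 1.91e-05). With an estimated correlation no list was called (lowest adjusted p = 0.437 with an estimated correlation). Fry called 7, the erythroid, amino acid transporter, labyrinth, fatty acid oxidation, water-soluble vitamin and selenoprotein lists (adjusted p = 0.0431) and glucose and lipid uptake (0.0482).

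At 33C edgeR called 486 genes for diet, 345 higher and 141 lower on MMV, with 3904 at an unadjusted p under 0.05, and with library size alone 1232 were higher and 129 lower. It called 0 with the erythroid or the labyrinth covariate, 1 with the rRNA-related covariate and 0 when only the groups compared were fitted. The median ratio of the 486 genes' log2 fold changes to the first fit was 52.5%, 52.1%, 92.7% and 100% in these settings. That ratio was 96.9% without the 3 libraries with high inflammatory scores, which leaves a single pool in MMV.33C.Male. Leaving out a library moved the count by over 1.5 times in 16 cases. It gave 217 and 311 without Control.22C.Female 1 and 3, and 212 without Control.22C.Male 3. It gave 0, 117 and 991 without Control.33C.Female 1, 2 and 3, and 0, 1275 and 0 without Control.33C.Male 1, 2 and 3. The count was 785 without MMV.22C.Female 3, 1012 without MMV.22C.Male 3. It was 2132, 0 and 44 without MMV.33C.Female 1, 2 and 3, and 0 and 96 without MMV.33C.Male 2 and 3.

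At 22C diet changed 1 gene, with 1191 at an unadjusted p under 0.05, 6 called by DESeq2 and 0 by limma-voom. Dclk2 (ENSMUSG00000028078, chromosome 3, 86786151 to 86920852) fell from 12.6 ± 2.94 to 6.83 ± 1.36 CPM (SD, n = 6), a log2 fold change of -0.89 ± 0.14 (adjusted p = 0.0484, 6 of 6 pools). This count was 1 without Control.22C.Female 1, 2 or 3 or MMV.22C.Female 2 and 0 without each of the other 20 libraries. Mmp12 (-1.04 ± 0.19, adjusted p = 0.35) and Fbln1 (-0.63 ± 0.14, adjusted p = 0.614) came next with Ppp1r7 (0.22) and Foxn3 (0.23). The 19 endoplasmic reticulum stress genes were all negative with a median of -0.35, 0 called over all genes and 14 lower adjusted over the list alone (camera adjusted p = 3.78e-16, and adjusted p = 0.806 with an estimated correlation). The genes called at 33C had a median absolute log2 fold change of 0.556 at 33C and 0.166 at 22C, and 410 of the 486 had the same sign of the edgeR estimate in the separate libraries at 22C. The larger number called at 33C was not shown to differ from that at 22C, since the interaction called 0 genes.

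Diet and heat combined were set against the Control diet at 22C. Il34, a macrophage growth factor, rose from 5.99 ± 0.809 to 15.9 ± 6.54 CPM (SD, n = 6; 1.41 ± 0.28, adjusted p = 0.0441). Bmper, a regulator of bone morphogenetic proteins, rose by 1.35, Slc9b2 by 1.34, Slc5a5, the iodide carrier, by 0.90, Aifm2 and Arhgef37 by 0.70, Acer2, a ceramidase, by 0.62 and Sik1, a salt-inducible kinase, by 0.61. Mmp12 fell from 29.1 ± 5.35 to 12.8 ± 3.06 CPM (-1.19 ± 0.20, adjusted p = 0.0325). Next came Zmat4 (-0.83), Cma1, mast cell chymase (-0.71), Nrep (-0.69), Fbln1 (-0.66), Dclk2 (-0.64), Serpinh1 (-0.60) and Aplp1 (-0.55). All 16 lay on the same side of the Control mean in 6 of 6 pools. Among 35 respiratory chain genes Ndufs8 fell (-0.26 ± 0.05, adjusted p = 0.0367, 6 of 6 pools) and 11 fell adjusted over the list alone, with a median of -0.08 (camera adjusted p = 1.84e-04, and adjusted p = 0.499 with an estimated correlation). The endoplasmic reticulum stress list had 19 of 19 negative values and a median of -0.40, with 0 called over all genes and 15 lower adjusted over the list alone (camera adjusted p = 4.33e-09, and adjusted p = 0.499 with an estimated correlation).

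For diet and heat combined edgeR called 57 genes in all, 27 higher and 30 lower, with 3258 at an unadjusted p under 0.05, and 627 higher and 65 lower with library size alone. It called 0 with the labyrinth or rRNA-related covariate and without the 4 libraries with low uterine gland scores, and 1 with the junctional zone covariate. The median ratio of the 57 genes' log2 fold changes was 83.4%, 90.3%, 95.6% and 95.8% in these settings. That ratio was 89.1% without the 3 libraries with high inflammatory scores, which leaves a single pool in MMV.33C.Male. Leaving out Control.22C.Female 1, 2 or 3 gave 3, 0 or 0 genes, and Control.22C.Male 1, 2 or 3 gave 0 each. Leaving out Control.33C.Female 1, 2 or 3 gave 27, 96 or 78, and Control.33C.Male 1, 2 or 3 gave 6, 14 or 40. Leaving out MMV.22C.Female 1, 2 or 3 gave 52, 93 or 129, and MMV.22C.Male 1, 2 or 3 gave 4, 19 or 96. Leaving out MMV.33C.Female 1, 2 or 3 gave 1263, 0 or 1, and MMV.33C.Male 1, 2 or 3 gave 23, 0 or 36.

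Between male and female placentas 13 genes differed, 8 higher and 5 lower in males, and most were sex-linked. Besides Xist (-2.72 ± 0.14), the genes lower in males were the X-linked Ogt, an enzyme of protein glycosylation (-0.63 ± 0.08, adjusted p = 5.93e-04), Taf1 (-0.50), Eif2s3x, a translation initiation factor with a Y copy (-0.48), and Pin4 (-0.45), each lower than the female mean in 12 of 12 pools. Pnpt1, an RNA-degrading enzyme of mitochondria, was higher in males (0.30 ± 0.05, adjusted p = 0.0263, 11 of 12 pools). Kdm5c missed the threshold (-0.38 ± 0.07, adjusted p = 0.0503, 12 of 12 pools), as did Kdm6a and Ddx3x. The 4 X-linked genes with Y copies had 1 called over all genes and 3 lower adjusted over the list alone, and camera called them with the preset correlation (adjusted p = 1.56e-10) and with an estimated one (adjusted p = 0.00371 with an estimated correlation). The 12 giant cell markers were all higher in males with a median of 0.19 and 0 called by either adjustment (camera adjusted p = 5e-06, and adjusted p = 0.163 with an estimated correlation). Only 503 genes had an unadjusted p under 0.05, fewer than the 858 given by chance.

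Sex did not change the response to heat or diet of any single gene past the threshold. For heat by sex edgeR called 0 genes, with 279 at an unadjusted p under 0.05, and for diet by sex 0, with 557. DESeq2 and limma-voom also called 0 in both. The smallest p-values were those of Sprr2d, Hnrnpf, Gm29084, Ier5l and Rhox1 for heat by sex and of Gm26917, Atp12a, Cldn1, Qsox2 and Slfn4 for diet by sex, each with an adjusted p of 1. In diet by sex all 19 interferon genes had positive interactions, that is, a more positive signed diet effect in males than in females, with a median of 0.68, 0 called over all genes and 11 adjusted over the list alone (camera adjusted p = 1.05e-17, and adjusted p = 0.412 with an estimated correlation). The interferon list mean stood apart in Control.33C.Female 2 (1.62) and MMV.33C.Male 1 (0.84), and the median was 0.27 without the 3 libraries with high inflammatory scores (these and MMV.33C.Male 2). Within a single sex, 10 comparisons of 3 against 3 called 1 gene in all. Sprr2d, a small proline-rich protein of epithelia, had 15, 22 and 14 counts in the Control females at 33C and 0 in all 3 at 22C (0.646 ± 0.118 CPM, adjusted p = 0.0315, 3 of 3 pools). DESeq2 called 477 and limma-voom 5288 over these comparisons, and edgeR called 157 without MMV.33C.Female 1, 13 without Control.33C.Female 3, 5 without Control.33C.Male 2 or MMV.33C.Male 3, 1 without 7 others and 0 without 13.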

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

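Of the tests reported here, those with the labyrinth list mean (pooled and for genes that rose or fell), with the rRNA-related level and on less uterine tissue, and the adjustment of the inflammatory test over lists, were chosen after the results were seen, and the split into rises and falls was made after the pooled value was known. In each interaction several gene lists differed in their response between groups by camera with the preset correlation. There were 13 lists for heat by diet, 5 for heat by sex and 8 for diet by sex. None of these calls held with an estimated correlation (lowest adjusted p = 0.618, 0.984 and 0.412 with an estimated correlation). Chance was not excluded, since 42, 95 and 75 of 100 splits of the libraries called as many lists, up to 20, 21 and 19.

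The genes called for diet were the first pattern weighed. If all pools are independent, chance was excluded, as no other split of 100 called any gene (1 as large, real 541, highest other 0). The splits reassigned conditions within each sex separately, so they cannot exclude chance if female and male pools share dams. The count was 40 without MMV.33C.Female 2. As far as their variation within groups can tell, the rRNA-related reads as the whole cause were argued against, since this covariate left 95% of the called genes' log2 fold changes (85.9 to 101 with a library left out). Their median size was 0.35 before and 0.33 after, with a median SE of 0.0794 and 0.0934. Only 3 genes stayed called because the SE grew. The covariate is fitted on libraries within groups, while the level also differed between whole groups (0.164 to 0.205% in MMV.22C.Male, 2.98 to 4.2% in MMV.22C.Female). A cause tied to this level that whole groups share could therefore not be tested. A larger labyrinth share of the tissue on MMV stays open: its list mean as a covariate left 59.8% over 539 genes (52 to 64.7 with a library left out), and 53% for 376 genes that rose (44.7 to 57.9) and 76.7% for 163 that fell (67 to 80.5), with median sizes from 0.35 to 0.20 (SE 0.079 and 0.0719), 0.38 to 0.20 (0.0878 and 0.0724) and 0.27 to 0.20 (0.0666 and 0.0668), so the calls ended with the smaller effects (smallest adjusted p = 0.201) and a shift in tissue cannot be told apart from a diet effect on these genes. Whether the diet effect at 33C is also present at 22C could not be decided either, as 409 of 486 genes had the same sign of the difference in mean log2 CPM (84.2%), but 52 of 400 reassignments gave as many (one-sided exact permutation p = 0.13).

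The inflammatory genes at 33C were the next pattern. The list mean was 0.51 ± 1.36 at 33C and -0.51 ± 0.40 at 22C (SD, n = 12), with 5 of 12 libraries at 33C above the highest at 22C, and a chance spread of a few libraries stays open: the two-sided exact permutation p of 0.014 over 160000 reassignments met the bound set for it, but the list was picked among 42 after its values were seen, and the p adjusted over these was 0.147. In the same permutation test over the 42 lists the respiratory chain list had the smallest p (0.00122, adjusted p = 0.0514). The neutrophil (0.00591) and interferon lists (0.00745) came next, with an adjusted p of 0.104 for both. Uterine tissue in the sample as the whole cause of the inflammatory difference was argued against, since its covariate left 92% of that difference (85.9 to 96.3). Neutrophil content may account for the inflammatory difference: the neutrophil list mean left -1.39% of it (-13.2 to 6.71), and within groups both means moved together (Pearson r = 0.92, permutation p = 3e-04; Spearman rho = 0.852, permutation p = 6e-04; 100000 resamples, 1 relation, r = 0.853 without Control.33C.Female 2 and MMV.33C.Male 3). Cells that release these cytokines and cells drawn by them would look alike, so the order of events, and an infection or a sampling difference, stay open.

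The 4 libraries at 22C with low uterine gland scores (Control.22C.Female 2, Control.22C.Male 2, MMV.22C.Female 2 and MMV.22C.Male 1) were the last pattern, at -1.24 to -0.93 against -0.38 to 1 in the other 20. Less uterine tissue in the sample is a candidate explanation, since 4 of 4 also lay below all other libraries in myometrium (-1.47 to -1.08 against a lowest of -0.56) and stromal markers (-1.13 to -0.62 against -0.51), lists that share Myh11, a smooth muscle myosin, at 57.4 ± 9.93 CPM in the 4 and 311 ± 115 in the 20. The abundant Muc1, Des, Dcn and Col3a1 were 1.05, 1.75, 1.41 and 1.29 times higher in the 20, and the placenta also expresses several of these. Decidual markers overlapped (-0.27 to -0.04 against -0.23 to 0.26). Xist counts were lowest among male pools in Control.22C.Male 2 (1242, depth 24.2 megacounts) and MMV.22C.Male 1 (1482, 28.1 megacounts). The next was 1492 in MMV.33C.Male 1, at 16.5 megacounts. Whether Xist in male pools came from maternal tissue was not tested. Female and male pools from the same dams, which would make pools of a condition match in pairs, could not be decided (one-sided exact permutation p = 0.583; mean match 0.305, median of 24 pairings 0.313), since the match was 0.539 and 0.448 in Control and MMV at 22C, the conditions of the 4 libraries, and 0.112 and 0.121 at 33C, but as high across diets at 22C (0.647 and 0.504), and how the tissue was dissected stays open too.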

How the results depend on the processing

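Covariates other than the erythroid list mean, and the sets of 4 and 3 libraries left out, were chosen after seeing the data. The counts of called genes for diet, diet at 33C and the combined comparison depended on tool, covariate and libraries, while the directions of named genes rarely did. Of 37492 values of named genes under alternatives, 34080 kept their sign and stayed on the same side of the threshold, 1812 fell below it and 1040 passed it. A further 560 changed sign with no call in either fit, and 0 changed sign with a call in either. Of 6888 list values, 5864 stayed, 407 fell below and 214 passed in the same direction, while 402 changed direction without being called in both fits. In 1 the direction changed with a call in both. There the cholesterol synthesis list for diet at 33C had a median of -0.14 with the labyrinth list mean as a covariate and 0.27 without. All 541 diet genes kept their sign under each alternative in which they were tested. They had been called on these same libraries, so a change of sign was unlikely from the start and this is no independent check. Size factors by RLE changed no count by over 1.5 times, and scaling shifted the median gene by at most 0.074. At these depths and 16 residual degrees of freedom the median SE was 0.0695 for 12 against 12 libraries and 0.139 for 3 against 3, which limits small changes within a sex. Where no cause is given below, the cause was not tested.

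With library size alone the counts were 0 for heat, 1723 for diet, 1361 for diet at 33C and 692 for the combined comparison. DESeq2 called 101 for heat, 1339 for diet, 10 for heat by diet, 67 for heat on Control, 9 for heat on MMV, 6 for diet at 22C, 1360 at 33C, 631 combined and 477 within a sex. Limma-voom with quality weights called 2948 for diet, 1 for heat by diet, 4 for heat on Control, 0 for diet at 22C, 3477 at 33C, 3796 combined and 5288 within a sex. Without a filter on low counts the counts were 0 for heat, 337 for diet, 206 at 33C and 15 combined, and at a mean log2 CPM of at least 1 they were 102 combined and 0 within a sex. With sex as an additive term they were 923 for diet, 0 at 22C, 933 at 33C and 214 combined. When only the groups compared were fitted, 0 were called for diet at 22C, 0 at 33C, 32 combined and 41 within a sex, with fewer libraries to estimate the spread. An absolute log2 fold change of at least 0.5 left 0 for heat, 163 for diet, 273 at 33C and 25 combined, and an adjusted p under 0.1 gave 1555 for diet, 1704 at 33C and 528 combined.

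With the erythroid list mean as a covariate the counts were 0 for heat, 4 for diet, 0 at 22C, 0 at 33C and 3 within a sex. With the uterine gland mean they were 0 for heat, 915 for diet, 805 at 33C and 2 within a sex. With the junctional zone mean they were 0 for heat, 855 for diet, 0 at 22C, 1146 at 33C, 1 combined and 3 within a sex. With the labyrinth mean they were 0 for diet, at 22C, at 33C, combined and within a sex. With the labyrinth, junctional zone and uterine gland means together they were 0 for heat, 36 for diet, 0 at 33C, 0 combined and 30 within a sex. With the rRNA-related level they were 0 for heat, 3 for diet, 1 at 33C, 0 combined and 459 within a sex. Without the 4 libraries with low uterine gland scores they were 0 for heat, 1 for diet, 23 at 33C, 0 combined, 7 for sex and 0 within a sex. Without the 3 with high inflammatory scores MMV.33C.Male keeps a single pool, so counts are not given for that set.

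With each library left out in turn, counts ran from 0 to 2 for heat, 40 to 1673 for diet (20 of 24 moved by over 1.5 times), 0 to 1 for heat on Control, 0 to 1 for diet at 22C, 0 to 2132 for diet at 33C (16 of 24), 0 to 1263 combined (21 of 24), 10 to 14 for sex and 0 to 157 within a sex. Diet calls were fewest, 40, without MMV.33C.Female 2 and most, 1673, without MMV.33C.Female 1. Diet calls at 33C were 0 without Control.33C.Female 1, Control.33C.Male 1, Control.33C.Male 3, MMV.33C.Female 2 or MMV.33C.Male 2. Heat by diet, heat on MMV, heat by sex and diet by sex stayed at 0 by edgeR in all 24 (1312, 1385, 279 and 557 at an unadjusted p under 0.05). No paired analysis was possible because replicate numbers are accession order only.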

Other observations

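The tests of library splits given here were planned before the data were examined, and the uterine gland and myometrium lists were added after principal components had been seen. The uterine gland list had a median log2 fold change of -0.17 for diet, with 0 of 7 members called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.736), and the myometrium list one of -0.07, with 0 of 9 by either adjustment (0.687). The first principal component, 27% of variance, had the uterine gland genes Kap, Cuzd1, Prap1 and Mmp7 at one end and Gcm1 among those at the other. The 13 mitochondrially encoded genes held 0 counts in every library.

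Hypoxia and glycolysis genes had positive medians for heat on the MMV diet. Of 24 hypoxia response genes 22 were positive with a median of 0.24, with 0 called over all genes or adjusted over the list alone (camera adjusted p = 2.08e-07, and adjusted p = 0.423 with an estimated correlation). Of 18 glycolysis genes 16 were positive with a median of 0.28, with 0 called over all genes and 4 adjusted over the list alone (camera adjusted p = 1.08e-06, and adjusted p = 0.423 with an estimated correlation). The 11 natural killer and T cell markers were all positive with a median of 1.03 and 0 called by either adjustment (3.6e-06, and adjusted p = 0.423 with an estimated correlation). The natural killer and T cell list mean was lowest in the 4 libraries with low uterine gland scores and Control.33C.Female 1, at -1.64 in MMV.22C.Female 2 and -1.01 in MMV.22C.Male 1, and without the 4 the median was 0.62, with 10 of 11 positive. From MMV at 22C to MMV at 33C the hypoxia and glycolysis list means went from -0.09 ± 0.13 and -0.08 ± 0.15 to 0.14 ± 0.16 and 0.14 ± 0.15 (SD, n = 6). Labyrinth and erythroid means went with them, from 0.03 ± 0.43 and -0.02 ± 0.55 to 0.40 ± 0.44 and 0.47 ± 0.52. In MMV.22C.Male 3 the hypoxia, labyrinth and erythroid means were -0.30, -0.67 and -0.86, and in MMV.33C.Male 2 they were 0.34, 0.63 and 0.82.

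Other splits of the libraries, 100 with the real one, showed which counts of genes chance can give. With all libraries, no other split called as many genes for diet at 33C (486, highest other 138, 1 split as large). The same held for the combined comparison (57, highest other 2, 1 as large). Chance would be excluded in both only if all pools are independent, which is not established. Splits within each sex cannot exclude it if female and male pools share dams. Without Control.33C.Female 1, Control.33C.Male 1, Control.33C.Male 3, MMV.33C.Female 2 or MMV.33C.Male 2 the count at 33C was 0, however. The combined count was 0 without Control.22C.Female 2 or 3, Control.22C.Male 1, 2 or 3, MMV.33C.Female 2 or MMV.33C.Male 2. For sex the share was under 0.05 (13 genes, 4 as large), but other splits called up to 1903, so chance was not firmly excluded by that count. That most of the 13 genes were sex-linked does not rest on the splits. For heat and diet at 22C the share was also under 0.05 (3 as large each), but it rests on 1 gene each, other splits called up to 102 and 23, and the count was 0 without 17 and 20 of the 24 libraries in turn, so chance was not firmly excluded. Such splits with many calls point to a structure of the samples, and what they share was not tested. It was not excluded within a single sex (1 gene, 19 as large, up to 2713). For the interactions and heat on each diet edgeR called 0 genes, so that all 100 splits had as many by construction and say nothing about chance. The highest other counts there were 1 for heat by diet, 485 for heat on the control diet, 1 for heat on MMV, 2 for heat by sex and 3 for diet by sex.

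The number of gene lists called by camera with the preset correlation was 21 for diet at 33C (highest other 19, 1 split as large). Chance was not firmly excluded there, since the margin was small and independence of all pools is not established. For heat on the MMV diet it was not firmly excluded either (17, highest other 19, 4 as large). Another split exceeded the 17, and several such counts were judged without adjustment. In heat on the MMV diet and diet at 33C 0 lists were called with an estimated correlation (lowest adjusted p = 0.423 and 0.437 with an estimated correlation). Chance was not excluded for heat (15 lists, 19 as large, up to 21), diet (12, 51 as large, up to 21), heat on the control diet (11, 56 as large, up to 19), diet at 22C (5, 97 as large, up to 20), the combined comparison (18, 6 as large, up to 19) or sex (5, 94 as large, up to 19). The median random split called 10 to 12 lists, so members of a list moved together across these pools whatever the grouping.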
